A study of Arabidopsis thaliana with 12 samples.

How the data were processed

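The values are gene expression intensities of 12 ATH1 arrays, as deposited. Per the submitters' processing notes, the authors computed MAS5 signals with Affymetrix Expression Console, and the versions are not given in the sources used here. The deposited intensity is 1 linear signal per probe set and array, not log2 values. On each array the mean without the highest and lowest 2% of signals lay between 1000.08 and 1000.09, so the authors had scaled all arrays to the same trimmed mean. Array medians lay between 375 and 442. No 2 arrays held identical values. Per the labels, total RNA came from seedlings 8 days old, and each array is 1 biological replicate.

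Of 22810 probe sets 64 are controls, and the other 22746 were tested. Each signal had 16 added and was taken to log2. The 4 group means were estimated in 1 linear model of the 12 arrays with limma 3.58.1 in R 4.3.3, and 5 contrasts were taken from it: FUS3 against WT without sucrose, FUS3 against WT with sucrose, sucrose against none in WT, sucrose against none in FUS3, and the interaction, which is the second contrast minus the first. Variances were moderated with a trend on mean level. P-values were adjusted after Benjamini and Hochberg over the 22746 probe sets of a contrast, and a probe set was called at an adjusted p under 0.05. Every SE of a single probe set is the moderated one of that model. The SE of a median over genes is the SD over those genes divided by the square root of their number, which treats genes as independent. The SE between arrays given for the plastid lists is that of a t test. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

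Probe sets were given genes from the probe table of the array design supplied with the data. It lists 14016 of the tested probe sets, 13513 with 1 gene and 503 with several. The other 8730 were tested and counted without a name. Positions are those of the gene in the TAIR10.1 annotation, where 13436 probe sets were matched. FUS3 and most loci of the gene lists are not among the listed genes and were not analysed here.

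The 25 gene lists, 412 loci in all, were written before the data were examined. Of these loci 80 were measured, which here means that the probe table names a probe set for that locus alone. Each locus was represented by its probe set with the highest mean among those of that locus alone. The minimum of 3 measured members for a test was set after the probe table was read, and so were 13 further lists built from gene symbols, before any model was fitted. Lists with 1 or 2 measured members are given as values, and 5 lists had none. The tested lists were compared with the rest of the 13355 named loci by camera in limma, with a correlation between genes preset to 0.01 and, beside it, with the correlation estimated for each list. Adjustment was over 60 tests for the planned lists and over 65 for the added ones.

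The genes named in the text follow a rule written before the data were examined: FUS3, in each contrast the 5 largest increases and 5 largest decreases among called probe sets that name 1 gene and whose groups do not overlap (a condition not set for the interaction), and up to 4 called members with the smallest adjusted p of each list described. A list is described where camera calls it or where at least 1/3 of its members are called. Other members of the lists that the text names were added after their values were seen. Where a locus has several probe sets, a differing value is given.

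RNA quality was read from 6 ratios of 3 prime to 5 prime control probe sets for actin, GAPDH and ubiquitin, in 24 exact permutation tests. The expected number beside an overlap is the product of both counts divided by the number of probe sets tested. Alternatives to the choices above were planned before the data were examined: 1 or 64 added instead of 16, quantile normalization, subtraction of the array median, a filter that leaves out 40% of the probe sets, only the arrays of the compared groups, a replicate block, a linear model without moderation, no trend, a 2-fold minimum and leaving out each array. Leaving out arrays for the gene list tests was chosen after seeing the data.

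The procedure was tested on simulated data in which 200 probe sets were changed. For FUS3 against WT without sucrose it recovered 63% of those changed by log2 1 and 99% of those changed by log2 2, with 12 false calls. For FUS3 against WT with sucrose it recovered 70% and 97%, with 9 false calls, and for the interaction 58% and 92%, with 12. A list of 12 genes shifted by 1 was called at an adjusted p of 3.002e-30 and 0 of 24 other lists were. Noise was drawn independently for each probe set, while the correlation estimated for the real lists reached 0.61. The simulation therefore does not tell how often lists of genes that vary together are falsely called.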

Results

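Transcript levels were measured in Arabidopsis thaliana seedlings with ATH1 arrays, which read each transcript through a set of short probes and give 1 signal per probe set. The seedlings were 8 days old and were grown on medium without sucrose or with 1.5% sucrose. They were wild type (WT) or line 2-8, which expresses FUSCA3 (FUS3) when given estradiol and is called FUS3 here. FUS3 is a B3-domain transcription factor that normally acts in developing seeds and promotes their maturation. There were 12 arrays, 3 for each of the 4 groups, and the labels call the samples of a group biological replicates. The labels name 5 µM estradiol for the medium of the FUS3 line, while the design text puts both lines under inducing conditions. Whether WT received estradiol is therefore not settled by the labels, and a FUS3 effect below is that of the line under inducing conditions against WT. With 3 arrays per group the median standard error (SE) of a log2 difference was 0.15, and that of an interaction 0.22. The number of arrays limits the precision of every value below.

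FUS3 itself comes first among the genes that bear on the design. The probe table used here names genes for 14016 of the 22746 tested probe sets and FUS3 is not among them, so its transcript was not analysed here. PAP85, a vicilin-like seed storage protein gene (AT3G22640, chromosome 3, 8011724 to 8013941), had mean signals of 63.3 ± 8.32 (SD, n = 3) in WT without sucrose and 29.9 ± 6.70 in WT with sucrose. In FUS3 its signals were 3985 ± 169.6 without and 32316 ± 562 with sucrose. Log2 changes below were taken after 16 was added to each signal, so they understate changes between 2 groups for transcripts with low signal. An interaction is a difference of 2 such changes and can be made smaller or larger by the 16 added. Of the 25 gene lists drawn up before the data were examined, 12 had at least 3 measured members and were tested, and 8 had 1 or 2 and are given gene by gene. The measured members, 80 of 412 loci, are a part of each list only. Measured here means that the probe table names a probe set for that locus alone. Other loci may be among the probe sets without a name.

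**Figure D1:**
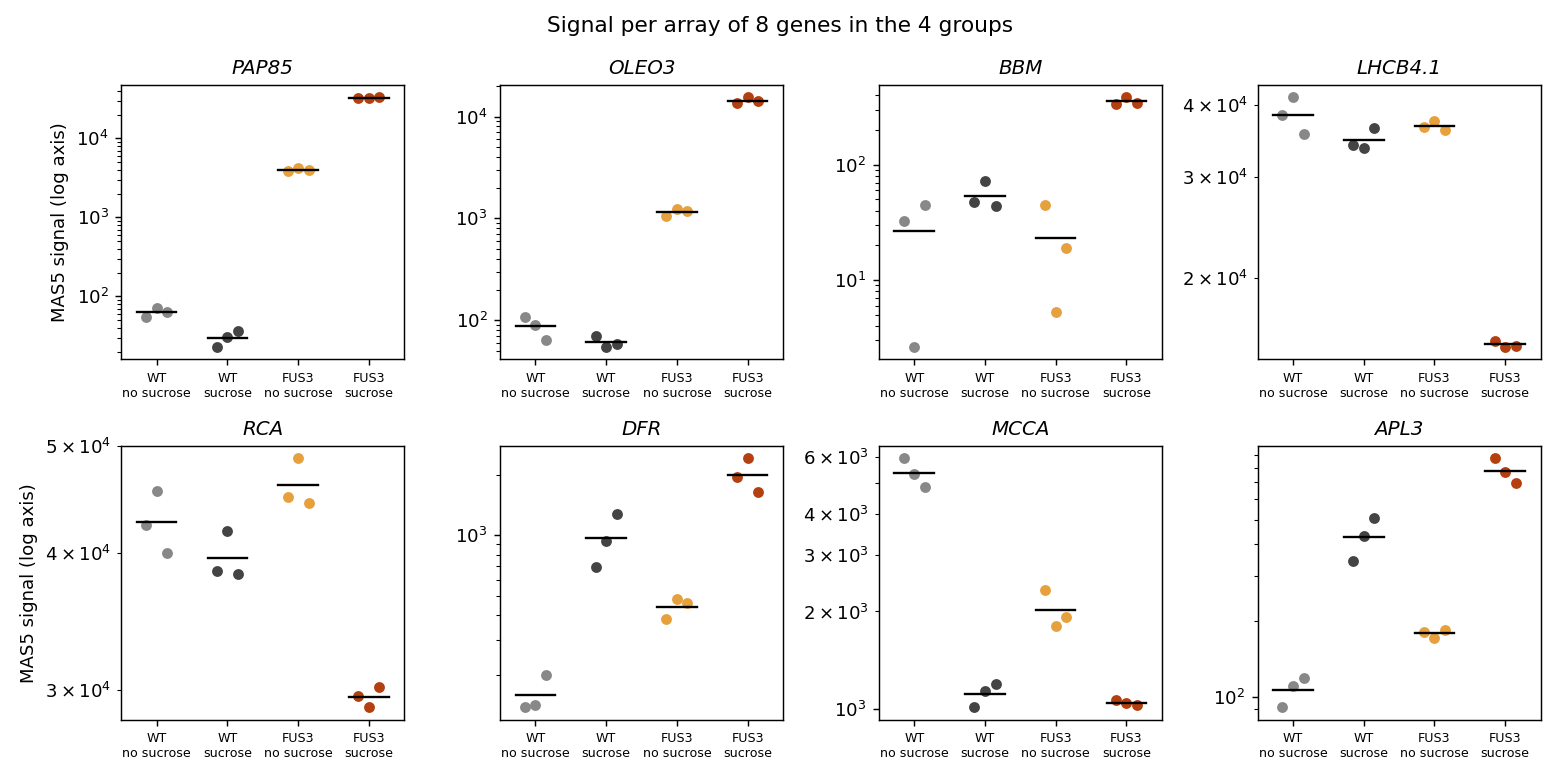
MAS5 signal on a log axis of 8 genes in the 4 groups of seedlings, where each point is 1 array and the bar is the mean of 3. PAP85 averaged 63.3 in WT without sucrose and 32316 in FUS3 with sucrose, and LHCB4.1 averaged 38475 and 15313.

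The first comparison asked what FUS3 does to seedlings without sucrose. Seed transcripts were among those that rose most. Of the 5 measured seed storage protein genes 4 rose, with a median log2 change of 5.66 (SD 2.40 over the 5 members). PAP85 rose by 5.66 (SE 0.11), the cupin genes AT2G28490 by 6.10 (SE 0.37) and AT4G36700 by 5.99 (SE 0.19) and the cruciferin-type 12S globulin gene AT1G03890 by 4.40 (SE 0.17), from a signal of 4.57 ± 2.56 to 422 ± 75.3. The cupin gene AT2G18540 did not pass at 0.39 (SE 0.23). All 8 lipid droplet protein genes rose, with a median of 2.22 (SD 1.53), the oleosin genes OLEO3 by 3.52 (SE 0.15) and AT3G01570 by 4.81 (SE 0.23). The calls of LDAP1 and SEIPIN1, at 0.48 (SE 0.12) and 1.16 (SE 0.30), were lost without replicate 2 of FUS3 (adjusted p = 0.0617 and 0.0787) or replicate 1 of WT (0.0683 and 0.0601), and that of SEIPIN1 also without replicate 3 of FUS3 (0.0667). Of 12 genes for late embryogenesis abundant (LEA) and desiccation proteins 9 rose, with a median of 2.80 (SD 1.67), AT3G15670 by 5.74 (SE 0.30) and AT4G21020 by 3.93 (SE 0.18). M17, AT3G22490 and AT3G53040 did not pass, at 0.06 (SE 0.25), 0.12 (SE 0.34) and 0.93 (SE 0.33), but AT3G53040 did without replicate 3 of FUS3 (adjusted p = 0.0145) and with a replicate block (0.0384). Among 3 seed maturation regulators the bZIP factor gene EEL rose by 1.36 (SE 0.14), while bZIP53 had -0.01 (SE 0.08) and BBM, an embryogenesis factor gene of the AP2 class, -0.10 (SE 0.42). In triacylglycerol assembly GPDHC1 rose by 0.49 (SE 0.09) and the acyltransferase gene PDAT2 had 0.20 (SE 0.36).

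Large changes were not limited to the seed lists above. ICL, which encodes isocitrate lyase of the glyoxylate cycle (AT3G21720, chromosome 3, 7652487 to 7656053), rose by 6.99 (SE 0.23), from 15.6 ± 10.9 to 3867 ± 550.2. AT1G47540 (chromosome 1, 17455533 to 17456186), a member of the added list of other seed-expressed transcripts, rose by 8.88 (SE 0.33), from a WT signal of 14.7 ± 18.1, so the size of its change depends on the 16 added. AT2G34700 of the pollen Ole e 1 family rose by 6.78 (SE 0.23) and the thionin gene AT2G15010 by 6.09 (SE 0.21). AT4G08050, a pseudogene in the reference table, fell by 2.89 (SE 0.21), from 111 ± 24.6 to 1.01 ± 0.115, and SWEET10, a sugar transporter gene, fell by 2.48 (SE 0.24), the extensin gene AT2G15880 by 1.85 (SE 0.27), AT4G37220 by 1.72 (SE 0.24) and AT3G46370 by 1.67 (SE 0.30). All 4 measured sugar starvation-induced genes, of 23 on the list, fell, with a median of -0.91 (SD 0.33). The 4 are MCCA, MCCB, IVD and ETFQO in every comparison. Others of the list, DIN1, DIN6 and STP1 among them, were not available by name in the probe table and were not analysed here. These calls therefore do not speak for sugar starvation genes at large. MCCA and IVD, of leucine breakdown, fell by 1.41 (SE 0.10) and 0.97 (SE 0.08). Flavonoid and anthocyanin synthesis rose in 5 of 6 genes with a median of 1.17 (SD 0.56), DFR by 1.38 (SE 0.20) and the anthocyanin glycosyltransferase gene UGT75C1 by 1.31 (SE 0.22). The call of 5MAT was lost without replicate 2 (adjusted p = 0.102) or 3 (0.0824) of FUS3 or replicate 2 (0.0948) or 3 (0.0519) of WT. The root hair genes EXPA7 and EXPA18 rose by 0.95 (SE 0.19) and 0.84 (SE 0.15). Of 8 photosynthesis genes only SBPASE rose, by 0.33 (SE 0.08), and the median was 0.01 (SD 0.16). APL3, for a subunit of ADP-glucose pyrophosphorylase, rose by 0.67 (SE 0.16) as 1 of 3 starch genes, and 2 of 9 plastid fatty acid synthesis genes rose and 1 fell. AT2G22230 rose by 0.38 (SE 0.07). FATA1 rose by 0.54 (SE 0.14), a call lost without replicate 2 of FUS3 (0.0702) or replicate 1 (0.0614) or 3 (0.0690) of WT. AT2G34590 fell by 0.27 (SE 0.07), a call lost without replicate 1 of FUS3 (0.0856) or replicate 1 (0.105) or 2 (0.0706) of WT.

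In all, 3758 probe sets were called for FUS3 without sucrose, 2160 higher and 1598 lower, of which 528 and 144 changed at least 2-fold. With the median of each array subtracted, the split became 1739 higher and 2091 lower, so which direction prevails depends on the scaling. Without replicate 1 of WT without sucrose the count was 2418. The camera test called 5 of the 12 lists: seed storage proteins (adjusted p = 2.89e-12), lipid droplet proteins (1.05e-12), LEA and desiccation proteins (2.79e-14), sugar starvation-induced genes (6.94e-09) and flavonoid and anthocyanin synthesis (1.48e-04). The flavonoid call was lost at adjusted p = 0.109 with an estimated correlation, and the other 4 held. Photosynthesis (adjusted p = 0.975), plastid fatty acid synthesis (0.892, median -0.05, mean 0.06), starch (0.340), guard cell and stomatal lineage genes (0.340) and reference genes (0.473) were not called. Of the reference genes GAPC2 rose by 0.22 (SE 0.07), a call lost with quantile normalization (adjusted p = 0.112) and without each of the 6 arrays compared (0.0674 to 0.125). The regulators had a median of -0.01 and a mean of 0.42 (adjusted p = 0.247). Fatty acid beta-oxidation with the glyoxylate cycle had a median of -0.22 and a mean of 2.04 (adjusted p = 0.989), since ICL rose and the lipase gene SDP1 fell by 0.65 (SE 0.09). Adjusted over the list alone, 10 LEA genes rose, 2 beta-oxidation genes fell and 1 reference gene, SAND, fell, and the other counts stayed the same.

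The second comparison put FUS3 against WT with sucrose, where the seed transcripts reached far higher levels. All 5 storage protein genes rose, with a median of 9.16 (SD 3.31), AT1G03890 by 9.85 (SE 0.17) to a signal of 18740.2 ± 992, PAP85 by 9.47 (SE 0.11) and AT4G36700 by 8.73 (SE 0.19). All 8 lipid droplet protein genes rose with a median of 6.46 (SD 3.06), OLEO3 by 7.55 (SE 0.15), from 61.1 ± 7.79 to 14377 ± 996, and LDAP2 by 5.53 (SE 0.20). All 12 LEA and desiccation genes rose with a median of 7.13 (SD 1.42), AT3G15670 by 10.31 (SE 0.30) and M17 by 5.55 (SE 0.25). EEL rose by 3.69 (SE 0.14) and BBM by 2.42 (SE 0.42), from 54.1 ± 15.4 to 354 ± 26.3. PDAT2 rose by 2.69 (SE 0.36) and GPDHC1 by 0.46 (SE 0.09). AT1G47540 rose by 10.19 (SE 0.33), AT3G63040 by 10.06 (SE 0.22) and ICL by 7.47 (SE 0.23), while SDP1 and AIM1 of the same list had 0.16 (SE 0.09) and 0.03 (SE 0.08).

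All 8 photosynthesis genes fell in FUS3 with sucrose, with a median of -0.84 (SD 0.43). The antenna protein gene LHCB4.1 fell by 1.18 (SE 0.07), from 34789 ± 1464 to 15313 ± 190.1, PSAN of photosystem I by 1.54 (SE 0.09) and RCA, for Rubisco activase, by 0.42 (SE 0.08). The chlorophyll synthesis genes CHLM and PORB fell by 0.96 (SE 0.10) and 1.17 (SE 0.13). Among 35 photosynthetic genes encoded in the plastid, a list added after the probe table was read, 21 fell and none rose, with a median of -0.77 (SD 0.62), rbcL by 1.38 (SE 0.23) and atpH by 2.49 (SE 0.36). Without sucrose 6 of the 35 fell, with a median of -0.32 (SD 0.40), a list call (adjusted p = 2.13e-04) lost at 0.572 with an estimated correlation. Without replicate 3 of FUS3 without sucrose the median was -0.09 and the list was not called (adjusted p = 0.133), nor were psaA, psbH and psbT of the 6 (0.101, 0.122 and 0.143). The calls of these genes were also lost without replicate 2 of FUS3 or replicate 1 or 2 of WT, all without sucrose (0.0644 to 0.125). Those of psbH and psbT were lost without replicate 3 of WT as well (0.0541 and 0.0648). In the same arrays the control probe set for 25S ribosomal RNA read 9915 ± 701 in FUS3 against 3491 ± 1023 in WT (exact p = 0.1, the smallest that 3 against 3 arrays allow), while without sucrose it read 2088 ± 478 against 2491 ± 455 (exact p = 0.3). Plastid transcripts and ribosomal RNA carry few or no poly(A) tails, so readings of both also depend on how the RNA was labelled. FAMA, of the guard cell lineage, fell by 1.89 (SE 0.21) and the trichome-patterning gene TRY by 1.74 (SE 0.24). The expansin gene EXPA8, counted with gibberellin response, fell by 1.63 (SE 0.10) and PDF1.2A, of ethylene response, by 1.85 (SE 0.39). Root hair EXPA7 and EXPA18 rose by 0.88 (SE 0.19) and 0.57 (SE 0.15), and the heat shock gene HSP17.6C by 1.28 (SE 0.45). The largest falls of named genes included AT1G76960 at -4.61 (SE 0.28), the peroxidase gene AT5G58390 at -4.57 (SE 0.21) and AT4G19430 at -4.05 (SE 0.32).

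Flavonoid and anthocyanin synthesis rose in 5 of 6 genes with a median of 1.05 (SD 0.45), UGT79B1 by 1.25 (SE 0.18) and DFR by 1.06 (SE 0.20). The call of 5MAT at 1.05 (SE 0.36) was lost without replicate 2 (adjusted p = 0.116) or 3 (0.0645) of FUS3 or replicate 2 (0.0651) or 3 (0.0859) of WT, all with sucrose. The starch genes APL3 and APL4 rose by 0.85 (SE 0.16) and 0.89 (SE 0.21), and SBE2.2 had -0.25 (SE 0.14), which passed without replicate 2 of FUS3 with sucrose (adjusted p = 0.0233). Of the 9 plastid fatty acid synthesis genes 3 rose and 4 fell, among them FATA1, up by 0.63 (SE 0.14), and FATB, down by 0.54 (SE 0.09). The rises of AT2G34590 and KAR, at 0.20 (SE 0.07) and 0.27 (SE 0.10), and the fall of LPD2, at -0.26 (SE 0.08), were lost without single arrays (adjusted p up to 0.164, 0.105 and 0.116), and both rises also with array medians subtracted (0.147 and 0.0719). Of the starvation-induced genes MCCA had -0.09 (SE 0.10), ETFQO fell by 0.40 (SE 0.09), and MCCB had -0.03 (SE 0.08). IVD rose by 0.27 (SE 0.08), a call lost without replicate 2 of FUS3 (adjusted p = 0.0588) or replicates 1 (0.0546) or 2 (0.0638) of WT, all with sucrose. None of the 4 reference genes changed, with a median of -0.01 (SD 0.07). The comparison called 8761 probe sets, 4300 higher and 4461 lower, of which 1124 and 1218 changed at least 2-fold. Camera called storage proteins (adjusted p = 8.20e-10), lipid droplet proteins (8.47e-12), LEA and desiccation proteins (4.95e-19) and photosynthesis (3.22e-08), and these held with an estimated correlation. Flavonoid synthesis (0.00933) was lost at adjusted p = 0.236 with an estimated correlation. The regulators (0.0448) were lost at adjusted p = 0.115 with an estimated correlation, at 0.0620 without replicate 3 of FUS3 with sucrose and at 0.0597 without replicate 3 of WT with sucrose. Plastid fatty acid synthesis (0.549, median 0.01, mean -0.06), starch (0.345), starvation-induced genes (0.764), guard cell genes (0.340) and reference genes (0.912) were not called. Beta-oxidation (0.0728) was called at 0.0417 without replicate 3 of FUS3 and at 0.0344 without replicate 2 of WT, both with sucrose. The plastid-encoded list was called at 2.91e-08 and lost at adjusted p = 0.449 with an estimated correlation. Adjusted over the list alone, 24 plastid-encoded genes fell, and the counts of the 12 planned lists stayed the same.

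**Figure D2:**
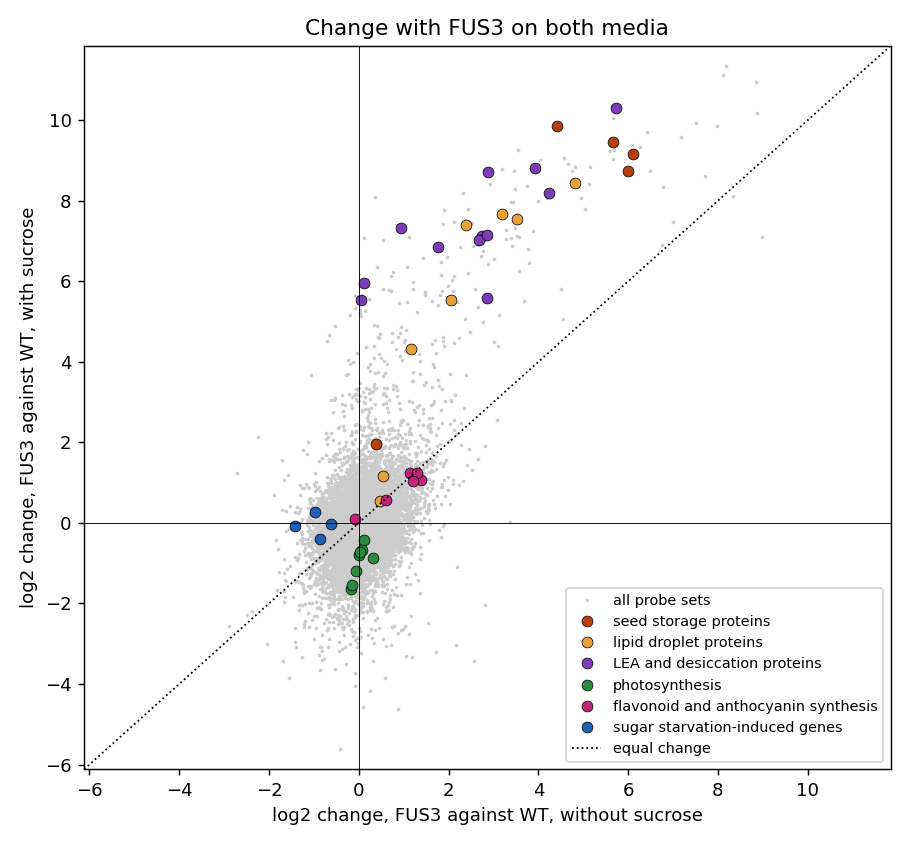
Log2 change of FUS3 against WT without sucrose (x axis) and with sucrose (y axis), where each grey point is 1 probe set, colours mark 6 gene lists and the dotted line marks equal change. Seed genes lie above the line, PAP85 at 5.66 and 9.47, and photosynthesis genes below it, LHCB4.1 at -0.06 and -1.18.

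The third comparison asked what sucrose alone does to WT seedlings. All 4 sugar starvation-induced genes fell, with a median of -1.56 (SD 0.65), MCCA by 2.26 (SE 0.10), from 5385 ± 553 to 1111 ± 92.9, and IVD fell by 1.95 (SE 0.08). Sugar represses these genes, which let cells draw on amino acids. Flavonoid and anthocyanin synthesis rose in 5 of 6 genes with a median of 1.49 (SD 1.01), DFR by 2.45 (SE 0.20), from 161 ± 34.5 to 968 ± 288, and UGT75C1 by 2.18 (SE 0.22). The starch genes APL3 and APL4 rose by 1.84 (SE 0.16) and 0.64 (SE 0.21), the call of APL4 being lost without replicate 1 (adjusted p = 0.0556) or 3 (0.0534) of FUS3 with sucrose, replicate 1 (0.165) or 2 (0.110) of WT without, or replicate 2 (0.0970) or 3 (0.128) of WT with sucrose, and with quantile normalization (0.191). ICL rose by 2.58 (SE 0.23) and SDP1 fell by 0.77 (SE 0.09). Seed transcripts stayed low: of the storage protein genes only PAP85 changed and fell by 0.79 (SE 0.11), of the lipid droplet genes only LDAP1 rose, by 1.28 (SE 0.12), and of 12 LEA genes only AT3G17520 rose, by 0.76 (SE 0.26). That last call held without replicate 2 of WT without sucrose and was lost without each of the other arrays (adjusted p = 0.0547 to 0.190). AT2G28490 did not pass at 0.80 (SE 0.37), but did at 1.42 without replicate 3 of WT with sucrose (9.89e-05), and OLEO3 did not at -0.40 (SE 0.15), but did without replicate 3 of WT without (0.00430) or replicate 1 of WT with sucrose (0.0430) and with quantile normalization (0.0139). LEA4-5 did not pass at 0.83 (SE 0.32), but did at 1.28 without replicate 1 of WT with sucrose (adjusted p = 0.00114) and with a replicate block (0.00727). Of 9 plastid fatty acid synthesis genes 2 rose and 4 fell, FATA1 rising by 0.88 (SE 0.14) and LPD2 falling by 0.59 (SE 0.08), while the calls of AT2G22230, AT5G10160 and FATA2, at 0.23 (SE 0.07), -0.27 (SE 0.08) and -0.26 (SE 0.09), were lost without single arrays of WT (adjusted p up to 0.0798, 0.136 and 0.104). EXPA7, EXPA18, EXPA8 and PDF1.2A rose by 0.93 (SE 0.19), 1.12 (SE 0.15), 0.82 (SE 0.10) and 1.22 (SE 0.39), GPDHC1 rose by 0.25 (SE 0.09), CHLM fell by 0.59 (SE 0.10) and the heat shock gene HSP22 fell by 0.76 (SE 0.26). OCT1, an organic cation transporter gene (AT1G73220, chromosome 1, 27538190 to 27540235), rose by 5.68 (SE 0.23), and PRX52 rose by 3.70 (SE 0.29). The largest falls included AT3G62950, AT4G15690, AT4G15680 and AT4G15700, all CC-type glutaredoxin genes, at -4.55 (SE 0.29), -3.39 (SE 0.34), -3.32 (SE 0.24) and -3.30 (SE 0.21). The glycine-rich protein gene AT2G05540 fell by 3.42 (SE 0.24), from 18502 ± 1305 to 1825 ± 718.

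Sucrose in WT called 5919 probe sets, 3618 higher and 2301 lower, of which 930 and 317 changed at least 2-fold. With the median of each array subtracted, the split was 2333 higher and 4235 lower and the median of all changes moved from 0.02 to -0.13, so which direction prevails depends on the scaling. Camera called starvation-induced genes (adjusted p = 2.69e-09), which held with an estimated correlation, and flavonoid synthesis (2.33e-04), lost at adjusted p = 0.115 with an estimated correlation. Photosynthesis had a median of -0.15 with 2 of 8 genes lower and was not called (0.0516), but was without replicate 2 of FUS3 with sucrose (0.0433), replicate 3 of WT without (0.0370) or replicate 2 of WT with sucrose (0.0463), and when 64 was added (0.0374). The 2 genes were PSAN at -0.26 (SE 0.09) and ATPC1 at -0.24 (SE 0.08), both lost with quantile normalization (adjusted p = 0.243 and 0.346) and without single arrays (up to 0.168 and 0.138), while LHCB4.1, LHCB4.2, RCA and PRK were also lower with array medians subtracted (0.00803, 0.0107, 0.0256 and 0.00274). SPCH, of the stomatal lineage, fell by 0.64 (SE 0.22), a call lost without single arrays (up to 0.198). Regulators (0.584), storage proteins (0.561), lipid droplet proteins (0.589), LEA proteins (0.912, median -0.06, mean 0.08), plastid fatty acid synthesis (0.371), starch (0.122), beta-oxidation (0.961), guard cell genes (0.223) and reference genes (0.431) were not called. Adjusted over the list alone no LEA gene rose, and the other counts stayed the same.

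The fourth comparison asked what sucrose does in FUS3 seedlings. All 5 storage protein genes rose, with a median of 3.02 (SD 1.50), AT1G03890 by 5.43 (SE 0.17) and PAP85 by 3.02 (SE 0.11). All 8 lipid droplet genes rose with a median of 3.55 (SD 1.53), OLEO3 by 3.62 (SE 0.15) and AT2G25890 by 5.33 (SE 0.23), and all 12 LEA genes with a median of 5.02 (SD 0.89), AT3G53040 by 6.33 (SE 0.33) and M17 by 5.41 (SE 0.25). EEL rose by 2.60 (SE 0.14), BBM by 3.37 (SE 0.42), PDAT2 by 2.92 (SE 0.36), GPDHC1 by 0.22 (SE 0.09) and ICL by 3.06 (SE 0.23). All 8 photosynthesis genes fell, with a median of -1.15 (SD 0.37), LHCB4.1 by 1.26 (SE 0.07) and RCA by 0.64 (SE 0.08), and CHLM and PORB fell by 1.45 (SE 0.10) and 0.63 (SE 0.13). Flavonoid synthesis rose in 5 of 6 genes with a median of 1.47 (SD 0.88), DFR by 2.13 (SE 0.20), and of 3 starch genes APL3 and APL4 rose by 2.02 (SE 0.16) and 1.37 (SE 0.21), while SBE2.2, of starch branching, fell by 0.41 (SE 0.14), a call lost without replicate 1 (adjusted p = 0.0722) or 3 (0.0805) of FUS3 without or replicate 1 (0.0626) or 3 (0.151) of FUS3 with sucrose. All 4 starvation-induced genes fell with a median of -0.71 (SD 0.27), MCCA by 0.93 (SE 0.10). In plastid fatty acid synthesis FATA1 rose by 0.98 (SE 0.14) and LPD2 fell by 0.80 (SE 0.08). FAMA fell by 1.89 (SE 0.21), TRY fell by 1.52 (SE 0.24) and EXPA8 by 0.76 (SE 0.10), while EXPA7 and EXPA18 rose by 0.86 (SE 0.19) and 0.85 (SE 0.15). Of the named genes AT3G58450 rose most, by 6.92 (SE 0.24), and AT5G66780 rose by 5.82 (SE 0.23). AT2G05540 fell most, by 5.14 (SE 0.24), followed by the glutaredoxin gene AT3G62950 at -3.65 (SE 0.29) and the peroxidase gene AT5G58390 at -3.38 (SE 0.21).

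Sucrose in FUS3 called 8939 probe sets, 4967 higher and 3972 lower, of which 1190 and 1162 changed at least 2-fold. With the median of each array subtracted, the split was 3257 higher and 5353 lower and the median of all changes moved from 0.04 to -0.11, so here too the scaling decides which direction prevails. Camera called storage proteins (adjusted p = 1.81e-06), lipid droplet proteins (1.58e-09), LEA proteins (1.33e-14), photosynthesis (1.58e-09) and starvation-induced genes (9.37e-04), which held with an estimated correlation, the last at 0.0499. Flavonoid synthesis (0.00379) was lost at adjusted p = 0.201 with an estimated correlation. Regulators (0.0574) and plastid fatty acid synthesis (0.0516, 1 rose and 4 fell) were not called. Leaving out replicate 1 of FUS3 without sucrose (0.0445), replicate 2 of FUS3 with sucrose (0.0467) or replicates 2 (0.0489) and 3 (0.0493) of WT without sucrose gave a call for the regulators. For fatty acid synthesis replicate 3 of FUS3 without (0.0492), replicate 2 of FUS3 with (0.0315) and replicates 1 (0.0397) and 3 (0.0458) of WT without sucrose did so. Starch (0.212), beta-oxidation (0.107), guard cell genes (0.181) and reference genes (0.764) were not called. Of the reference genes GAPC2 fell by 0.18 (SE 0.07), a call lost with quantile normalization (-0.01, adjusted p = 0.943). Adjusted over the list alone no reference gene fell, and the other counts stayed the same.

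The interaction asked whether the FUS3 effect differs between media. It was positive in all 5 storage protein genes, with a median of 3.06 (SD 1.43), 5.45 (SE 0.24) for AT1G03890 and 3.81 (SE 0.16) for PAP85, so FUS3 raised them more with sucrose. The call of AT2G28490, at 3.06 (SE 0.53), was lost at adjusted p = 0.145 when 1 instead of 16 was added to each signal, with a value of 2.59. The same held for 7 of 8 lipid droplet genes, with a median of 3.55 (SD 1.78) and 4.02 (SE 0.21) for OLEO3. It held for all 12 LEA genes, with a median of 4.73 (SD 1.00), 5.49 (SE 0.35) for M17 and 6.40 (SE 0.47) for AT3G53040. EEL had 2.33 (SE 0.19), PDAT2 2.49 (SE 0.51), and BBM 2.51 (SE 0.59), its call lost at adjusted p = 0.109 in the same way, with a value of 2.71. AT3G58450 had the largest value of a named gene, 6.97 (SE 0.34), with signals of 10.2 ± 6.82 in FUS3 without and 3119 ± 507 with sucrose. ICL did not pass at 0.48 (SE 0.33), but did at 1.50 (adjusted p = 2.21e-04) when 64 instead of 16 was added. All 8 photosynthesis genes had a negative interaction, with a median of -0.96 (SD 0.34), LHCB4.1 at -1.12 (SE 0.11), and so did CHLM at -0.87 (SE 0.15), PORB at -0.83 (SE 0.18), FAMA at -1.52 (SE 0.30), TRY at -1.94 (SE 0.33) and EXPA8 at -1.59 (SE 0.14). All 4 starvation-induced genes had a positive interaction, with a median of 0.92 (SD 0.44) and 1.33 (SE 0.14) for MCCA: FUS3 lowered them without sucrose, where WT signals were high, and MCCA hardly differed with it. None of the flavonoid genes passed, DFR at -0.32 (SE 0.29), nor did any starch gene, APL3 at 0.18 (SE 0.22). OCT1 had -4.87 (SE 0.32), AT1G76960 -5.49 (SE 0.40) and AT5G58390 -4.67 (SE 0.30), 3 transcripts that sucrose raised in WT and that FUS3 lowered with sucrose. The falls of AT3G60420, with an interaction of -4.43 (SE 0.62), came from 1 probe set, and its other probe set had -0.30.

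The interaction called 5253 probe sets, 2224 higher and 3029 lower, of which 826 and 1133 changed at least 2-fold. Camera called storage proteins (adjusted p = 1.98e-08), lipid droplet proteins (5.94e-10), LEA proteins (4.47e-19), photosynthesis (2.44e-09) and starvation-induced genes (6.21e-05), which held with an estimated correlation. The regulators (0.0341) were lost at adjusted p = 0.109 with an estimated correlation, at 0.0575 without replicate 3 of FUS3 with sucrose and at 0.0533 without replicate 3 of WT with sucrose. Flavonoid synthesis (0.912), starch (0.759), plastid fatty acid synthesis (0.340, 1 higher and 3 lower), guard cell genes (0.618, median 0.19, mean -0.36) and reference genes (0.764) were not called. Beta-oxidation (0.0607, median 0.48) was called without replicate 3 of FUS3 without sucrose (0.0492), of FUS3 with (0.0441), of WT without (0.0372) or of WT with sucrose (0.0498), and when 64 was added (0.00783). Adjusted over the list alone 4 fatty acid synthesis genes were lower, and the other counts stayed the same. WSD1 of wax synthesis passed in no comparison, with values from -0.66 (SE 0.38) to 1.05 (SE 0.38).

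**Figure D3:**
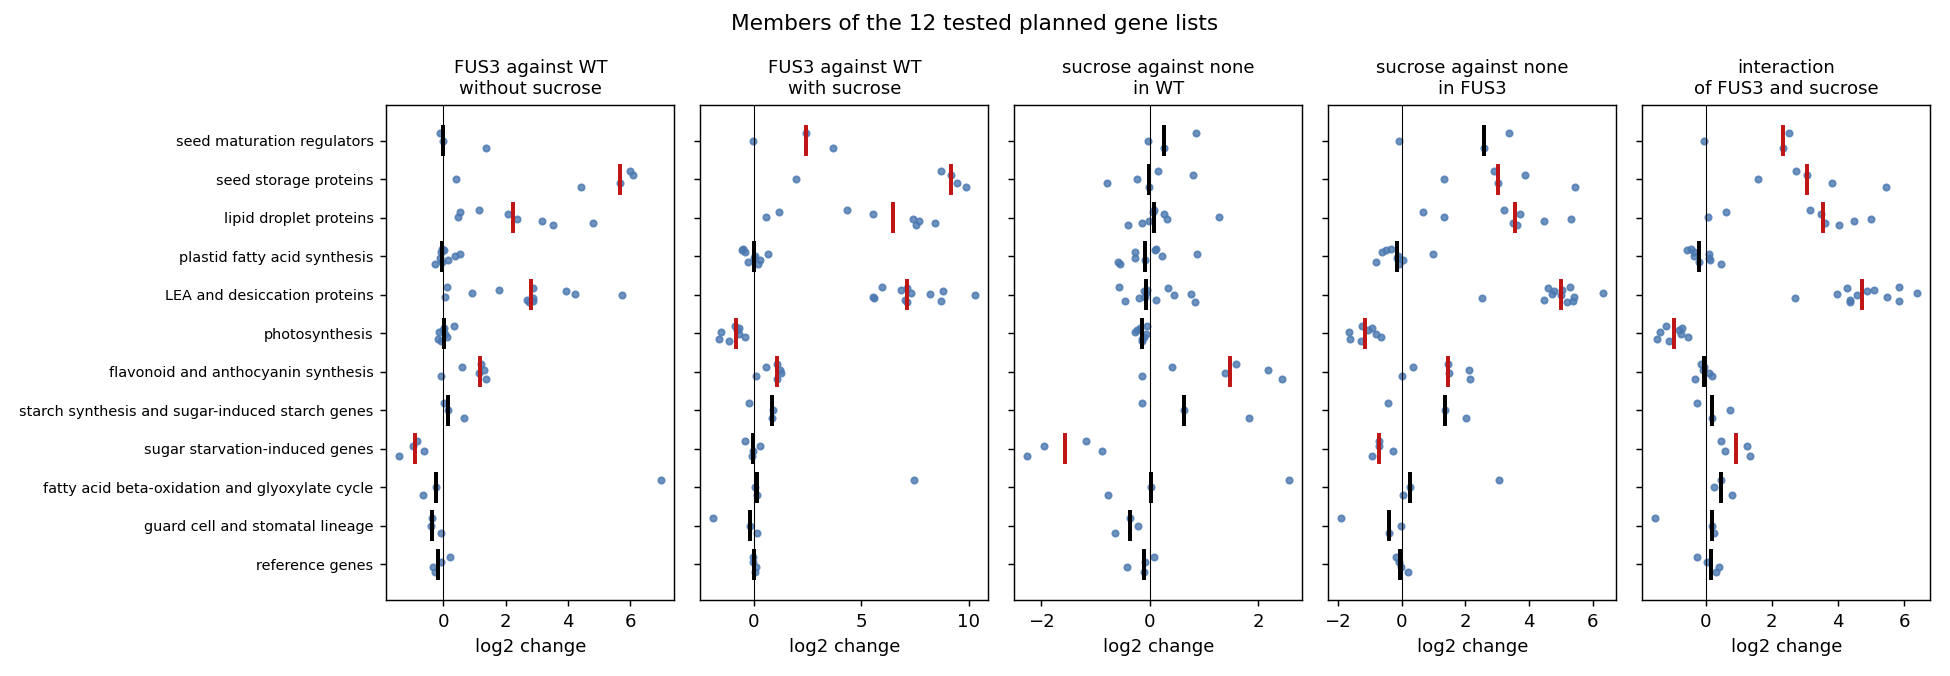
Log2 changes of the measured members (points) of the 12 tested gene lists in the 5 comparisons, with a bar at the median, red where camera gave an adjusted p below 0.05 and black otherwise. LEA and desiccation proteins go from a median of 2.80 without to 7.13 with sucrose for FUS3 against WT, and photosynthesis goes from 0.01 to -0.84.

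The genes that FUS3 changed overlapped between media. Of the probe sets higher in FUS3 without sucrose 1223 were also higher with sucrose, against 408.3 if the calls were independent, and 838 were lower in both, against 313.4. Opposite calls numbered 250 (423.6 if independent) and 171 (302.1). SWEET10 was lower in both, by 2.48 (SE 0.24) without and 2.29 (SE 0.24) with sucrose, and SBPASE was 1 of the genes with opposite calls. Sucrose raised 1807 probe sets in both lines (790.1 if independent) and lowered 1352 in both (401.8), DFR and MCCA among them. Opposite calls numbered 341 (631.8) and 227 (502.5), with EXPA8 and PAP85 as examples. The fall of PAP85 in WT lay between low signals, 63.3 ± 8.32 without and 29.9 ± 6.70 with sucrose. Whether it reflects the floor of the array was not tested, so PAP85 is a weak example of opposite regulation. Across probe sets, which are not independent replicates, the changes correlated at 0.546 for FUS3 and 0.319 for sucrose, and by rank at 0.284 and 0.352, so which of the 2 was more alike depends on the measure.

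Ratios of 3 prime to 5 prime control probe sets for actin, GAPDH and ubiquitin, a measure of RNA quality, differed between groups by -0.35 to 0.48 on the log2 scale. The smallest exact p was 0.1, reached in 6 of 24 tests, and 0.4 after adjustment. Group means of the ratios themselves ranged from -0.21 (GAPDH, second set) to 4.44 (actin, first set). For actin of the first set they were 3.95 or more in every group, and only differences between groups were tested. Signals of arrays of the same group correlated at 0.985 to 0.989, and those of FUS3 with sucrose with those of WT without sucrose at 0.908 to 0.917.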

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

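Of the tests in this part, those on low signals, on photosynthesis, on RNA degradation, on plastid number and on the labelling of the 25S ribosomal RNA were chosen only after the result was seen; the counts of other splits and the scaling test of the seed transcripts were not.

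What drew attention is that the FUS3 effect differs between media, in 5253 probe sets. Of 100 draws that reassign sucrose among the arrays of each line, the real one included, 1 gave as many, the highest other being 4737. That one was among the 11 other draws that kept the FUS3 arrays parted by medium. Draws that parted only the WT arrays reached at most 891, and those that parted neither at most 1. A draw that mixes the arrays of 1 line turns the contrast into the sucrose effect of the other, so these counts follow the size of those effects: they argue against the absence of any sucrose effect and do not decide whether the FUS3 effect differs between media. For the other comparisons the 10 splits of 6 arrays are too few for a share under 0.05: 1 of 10 gave as many in each, with real counts of 3758, 8761, 5919 and 8939 and highest other counts of 1, 0, 0 and 0, for FUS3 without sucrose, FUS3 with sucrose, sucrose in WT and sucrose in FUS3.

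The first pattern weighed is that FUS3 raised seed transcripts more with sucrose. Median interactions were 3.06 for storage proteins, 3.55 for lipid droplet proteins and 4.73 for LEA and desiccation proteins, 25 members in all. Low signals distort log2 changes and can shrink or exaggerate an interaction. The 16 members with a signal over 200 in FUS3 without sucrose had a median of 3.99 (SE 0.39), so the difference does not rest on members with low signals in that group. This filter did not cover the WT signals, which were low on both media for PAP85, and does not decide on the floor of the array in WT. Quantile normalization left the median of the members at 4.27, against 4.28 as deposited. Array medians lay between 375 and 442, so rescaling could move an interaction of this size only little. That outcome was therefore nearly fixed in advance, and it is the small spread of array medians that argues against scaling. More FUS3 transcript with sucrose stays open, since the induced transcript was not analysed here, and no biological explanation was tested.

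The second pattern is the fall of photosynthesis transcripts in FUS3 with sucrose, with a median interaction of -0.96, and of -0.70 and -0.48 for the added lists of nuclear and plastid-encoded photosynthetic genes (adjusted p = 2.62e-06 and 0.00124, and 0.119 and 0.631 with an estimated correlation). For FUS3 against WT with sucrose, scaling is argued against by a median change of -0.83 after quantile normalization, against -0.84 as deposited. The 4 reference genes, with a median of -0.01 (SD 0.07) there, also argue against it. For the interaction the reference genes spread more, with a median of 0.16 (SD 0.30) and values from -0.27 to 0.40. The 8 photosynthesis genes lay below these, from -1.48 to -0.53. Strong RNA degradation is argued against by a median difference of 0.089 in the 3 prime to 5 prime ratios. Single ratios differed by -0.16 (GAPDH, first set) to 0.24 (actin, first set). The latter and GAPDH of the second set, at 0.11, reached the smallest exact p of 0.1. Between FUS3 with and without sucrose the ratios differed by -0.35 to 0.48, so a smaller difference in RNA quality stays open. If fewer plastids lowered all plastid transcripts alike, ribosomal and polymerase genes of the plastid would fall as much as its photosynthetic genes. They lay 0.64 above them (medians of -0.13 for 19 and -0.77 for 35 genes). Taken per array the difference was 0.65 (SE 0.12 between arrays, exact permutation p = 0.1, the smallest that 3 against 3 arrays allow). Under that assumption this argues against fewer plastids as the only cause in the plastid-encoded genes. The test did not cover the nuclear photosynthesis genes. No biological explanation was tested, nor was a change in the mix of cells.

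The third pattern comes from data outside the comparisons: the 25S ribosomal RNA control read 2.84 times higher in FUS3 than in WT with sucrose, and 0.839 times WT without sucrose (exact p = 0.3). The same ratios, with a median difference of 0.089, read transcripts of actin, GAPDH and ubiquitin and not ribosomal RNA. They therefore do not decide whether RNA degradation raised the 25S reading. Stronger labelling of RNA without poly(A) tails might raise the 25S reading, but would also raise mitochondrial transcripts. The 15 genes encoded in the mitochondrion had a median change of 0.30 (SE 0.10), with 4 of their 22 probe sets called higher and 0 lower. That median is less than 0.77, which is 1/2 of the change of 1.54 in the mean log2 signal of the control. This argues against labelling as the whole cause and leaves a part open. A real increase in ribosomal RNA was not tested and stays open.

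Other differences between media are given as values. The median interaction was 2.33 for the seed maturation regulators and 4.18 for other seed-expressed transcripts, an added list, neither of which the tests of the first pattern covered. It was 0.92 for sugar starvation-induced genes, -0.32 for expansins and xyloglucan endotransglucosylases and -0.60 for glutathione S-transferases. The last 2 had adjusted p = 0.0224 and 0.00223, and 0.249 and 0.120 with an estimated correlation. Expansins were lost at adjusted p = 0.0728 without replicate 1 of WT without sucrose. Among single genes it was 6.97 for AT3G58450, 6.40 for AT3G53040, 5.99 for AT3G60730, 5.88 for AT5G07330, 5.84 for AT3G22490, -5.49 for AT1G76960, -4.87 for OCT1, -4.67 for AT5G58390, -4.43 for AT3G60420 and -4.43 for AT5G52760.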

How the results depend on the processing

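The gene list tests without single arrays were chosen only after the data were seen, and the other tests here were planned. Requiring at least 2-fold lowered the counts to 672, 2342, 1247, 2352 and 1959 in the order FUS3 without sucrose, FUS3 with sucrose, sucrose in WT, sucrose in FUS3 and interaction, by its construction. All other settings but 1 stayed within 1.5 times the reported counts: 3013 (no trend) to 3974 (replicate block) for FUS3 without sucrose, 7336 (without the 40% lowest probe sets) to 8959 (replicate block) for FUS3 with sucrose, 5265 to 6568 (array median subtracted) for sucrose in WT, 7648 to 9132 for sucrose in FUS3 and 4547 (model without moderation) to 5550 for the interaction. With single arrays left out the counts were 2418 (without replicate 1 of WT without sucrose, the exception) to 4018, 7701 to 8863, 4540 to 6016, 7796 to 9133 and 4474 to 5009, and the cause was not tested. The replicate block gave 3974, 8959, 6124, 9132 and 5550. Arrays with the same number correlated at a median of 0.028 (-0.007 to 0.111, 18 pairs) after group means were removed and others at -0.019 (-0.095 to 0.049). For 10 of 12 arrays the mean correlation with arrays of other groups was highest for their own number, where any of the 3 numbers could have been highest. Not every pair exceeded 0.1, the bound set for a paired model, so replicates were not treated as pairs. A weak factor shared by arrays of the same number stays open, and the block raised the count in every comparison. No direction of a named gene or list reversed where it was called with either setting, and changes of sign among uncalled values were not counted. The direction prevailing among called probe sets did reverse with array medians subtracted, in 3 comparisons, and, for sucrose in FUS3, with quantile normalization (4240 higher, 4544 lower). Of 540 values of named genes and list members, 1 (64 added) to 21 (no trend) fell below the threshold and 0 to 14 rose above it, 9 and 14 of these with array medians subtracted. For gene list tests an estimated correlation ended 6 of 25 planned and 23 of 28 added calls, and the mean over all probe sets of a locus none. Quantile normalization ended 3 added calls and gave 1 planned call, 64 added gave 4, and the replicate block ended that of the regulators for FUS3 with sucrose (0.0554) and gave 2 added calls, of ribosomal proteins and polymerase of the plastid for FUS3 without sucrose (0.0333) and sucrose in WT (0.0285). The alternatives for the FUS3 probe set were not run, since it was not analysed here, and the arrays of 2 groups alone give no interaction. Low signals limit precision: with 1 instead of 16 added, the interactions of BBM and AT2G28490 kept values of 2.71 and 2.59, and their calls were lost (adjusted p = 0.109 and 0.145).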

Other observations

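The test of the hypothesis in this part was chosen only after the result was seen, and the gene families below were chosen after the probe table was read, before any model was fitted. Of 12 other seed-expressed transcripts 11 rose in FUS3 without sucrose, with a median of 3.87 (adjusted p = 1.60e-22, and 0.00527 with an estimated correlation), AT3G54940 by 5.68 (SE 0.20) and AT1G04560 by 4.80 (SE 0.18), and all 12 with sucrose, with a median of 8.32. Of 10 genes of the plastid NDH complex 6 fell in FUS3 with sucrose, ndhJ by 2.40 (SE 0.20), with adjusted p = 0.00386, and 0.456 with an estimated correlation. Among 14 SWEET sugar transporter genes, 4 rose and 5 fell in FUS3 with sucrose. SWEET10 fell by 2.29 (SE 0.24) and SWEET17, a vacuolar fructose transporter gene, by 1.34 (SE 0.08), while SWEET7 rose by 2.30 (SE 0.35) and SWEET3 by 2.18 (SE 0.33). Sucrose raised SWEET13 in WT by 2.52 (SE 0.25) and lowered SWEET2 by 1.42 (SE 0.12). The family was not called in any of the 5 contrasts. Of 20 beta-glucosidase genes, BGLU19 rose by 3.78 (SE 0.24) in FUS3 without and 6.46 (SE 0.24) with sucrose. BGLU33 fell by 2.21 (SE 0.11) and BGLU29 rose by 3.25 (SE 0.18) with sucrose. Sucrose in WT raised 10 of the 20 and lowered 1 (adjusted p = 0.00870, and 0.0891 with an estimated correlation).

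Of 25 expansin and xyloglucan endotransglucosylase genes 10 rose and 2 fell with sucrose in WT (adjusted p = 0.00484, and 0.160 with an estimated correlation), EXLB1 by 1.99 (SE 0.14) and EXPB3 by 1.58 (SE 0.11). Their interactions were -2.38 (SE 0.20) and -1.58 (SE 0.15), while EXPA20 had 1.72 (SE 0.20). Of 14 glutathione S-transferase genes 7 rose with sucrose in WT (adjusted p = 0.00131, and 0.119 with an estimated correlation), GSTU20 by 0.99 (SE 0.09), with an interaction of -1.34 (SE 0.13). In FUS3 without sucrose 8 of them rose, a list call (0.0136) lost at adjusted p = 0.188 with an estimated correlation and at 0.0609 without replicate 2 of that group. Of 29 serine carboxypeptidase-like genes 12 rose and 1 fell with sucrose in WT (adjusted p = 0.00582, and 0.0866 with an estimated correlation), and scpl31 fell by 2.65 (SE 0.18) in FUS3 with sucrose. Of 46 UDP-glycosyltransferase genes 15 rose and 9 fell in FUS3 with sucrose, UGT76E12 by 3.22 (SE 0.38), a list not called in any contrast. Cytosolic ribosomal protein genes rose in small steps: 33 of 59 in FUS3 without sucrose, with a median of 0.31 (adjusted p = 2.95e-16, and 0.0157 with an estimated correlation), and 42 with sucrose, with a median of 0.30 (7.98e-10, and 0.0615).

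The hypothesis is that FUS3 without sucrose moves genes that sucrose moves in WT, MCCA and DFR among them. Probe sets called in both numbered 1347 higher in both, against 343.6 if independent, and 916 lower in both (161.7), with 54 (218.5) and 47 (254.2) in opposite directions. Both comparisons share the arrays of WT without sucrose, which alone makes their changes covary. The covariance of the log2 changes over probe sets was 0.117, against 0.0206 to 0.0251 in 100 simulations with the same shared control arrays and no FUS3 effect. These simulations drew noise independently for each probe set and array, and noise of that kind in the shared arrays accounts for only a part of the covariance. A deviation common to the arrays of WT without sucrose was not simulated, so the shared arrays stay open as a source of the rest. Genes are not independent replicates, and a common response to faster growth was not tested.

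Some values belong to no comparison. Spike controls of replicate 3 of WT with sucrose lay -0.77 from the other arrays in the first set of 9 probe sets and -0.05 in the second, on the log2 scale.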
